A study of Mus musculus with 9 samples.

How the data were processed

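Transcript levels were measured in transferred pmel1 CD8+ T cells of 9 mice, with 1 whole-transcript array per mouse and 3 mice in each of 3 groups. A pmel1 T cell carries a transgenic receptor for a peptide of gp100, a protein of pigment cells and melanoma. Per the labels' protocols, each recipient mouse was given pmel1 cells bearing the Thy1.1 marker, 100 µg of human gp100 peptide into a vein, and 400 µg of antibody in total. The combination group received 200 µg of an agonist antibody to CD27 with 100 µg of antibody to PD-1 and 100 µg of antibody to PD-L1. Each of the other groups received its own antibodies and 200 µg of isotype control antibody. CD8+ cells of the spleen were taken on day 4 by depleting other cells on magnetic beads, and Thy1.1+ CD8+ cells were then sorted by flow cytometry, per the labels' protocols. No group with peptide and isotype control alone is among the samples, and every comparison is therefore between treatments.

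The deposited values were on the log2 scale, 1 per probe set and array, made by the authors with RMA in oligo 1.38.0, per the submitters' processing notes. RMA corrects background, normalizes probe values to a common distribution and summarises the probes of each probe set. Arrays were not pooled. The genome build behind the array's probe sets was not given in the sources used here, and no coordinates are printed. Gene names were taken from the platform's annotation of the probe sets, with symbols updated through a mouse gene table. Of 72688 probe sets in the table, 6732 were controls and 65956 measured transcripts. Of the transcript probe sets, 31085 named 1 gene, 1665 named several and 33206 named none. Probe sets that named several genes or none were left out of the main test, and 357 genes had more than 1 probe set, of which the one with the highest mean over the 9 arrays was kept. This left 30632 genes, tested without a filter on low values. For arrays, the number of mice limits the precision, and it was 3 in each group.

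Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values. A linear model with 1 mean per group was fitted to all 9 arrays, which leaves 6 residual degrees of freedom, and limma's moderated test was applied to each of 3 comparisons, two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 30632 genes, and a gene was called at an adjusted p under 0.05 with no minimum fold. Replicate numbers in the sample titles were not used in the main fit. Unless stated otherwise, an adjusted p of a gene comes from this fit. Levels are given as means with the SD over 3 mice, and differences on the log2 scale with limma's SE.

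Before the data were examined, 22 lists of pathway genes, 8 lists of markers of other cell types, the main fit, most of the alternatives and the rule for named genes were fixed. Lists with at least 5 measured genes, 29 in all, were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 29 lists. The erythroid list had 4 measured genes and is given as values. Camera asks whether a list moved more than the other genes did. Each list's median was also placed among 10000 lists of random genes of like mean, taken within 200 ranks on each side. Camera was repeated with a correlation estimated for each list, and limma's fry was run as an alternative. Counts of list members that passed are given over all genes and adjusted over the list alone.

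The rule for named genes took, for each comparison, the 10 genes with the largest rise and the 10 with the largest fall among those called whose arrays did not overlap between the groups. It left out symbols by how they begin or end, those of predicted genes, microRNAs, olfactory receptors, antigen receptor segments and small nucleolar RNAs that begin with Snor. A small nucleolar RNA with another kind of symbol, AF357399, was therefore kept. It added up to 4 called members of each fixed list, or the member with the largest change where none was called, and 17 genes fixed by name. Of those 17, 14 had a probe set of their own. Tcf7 was not named by any probe set used here, 1 further gene is not reported here, and the probe set of Cd27 also names a microRNA, so that its values are given for the probe set. In the comparisons with anti-PD-1/L1, no more than 2 members per list are named, by size of change. That limit was set for length after the values had been seen.

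The test was checked on simulated data with the array spread of each group and genes changed by known folds, 50 at each fold. For the combination against anti-CD27, 72% of genes changed by 1.5-fold and 90% of those changed by 2-fold were recovered, with 0 false calls among 140. For the combination against anti-PD-1/L1, 74% and 96% were recovered, and 51 of 199 calls were false (25.6%). For anti-CD27 against anti-PD-1/L1, 64% and 90% were recovered, and 20 of 157 calls were false (12.7%). With an equal spread in the simulation the false calls were 11 of 160, 13 of 157 and 8 of 145 for the combination against anti-PD-1/L1, the combination against anti-CD27 and anti-CD27 against anti-PD-1/L1. The real spread was unequal: the median SD over genes was 0.0682 in the combination, 0.0586 in anti-CD27 and 0.141 in anti-PD-1/L1. Control probe sets and other single measures of an array were compared between groups by an exact permutation test, two-sided, which cannot go below 0.1 with 3 arrays against 3.

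The alternatives fixed beforehand were all probe sets with a symbol as separate tests, all transcript probe sets, filters on the lowest 25% or 50% of genes by mean, limma's trended and robust prior, the 6 arrays of a comparison alone, the replicate number as a block, arrays centred on their medians, quantile normalization between arrays, array weights, each array left out in turn, and a minimum of 1.5-fold. Array weights estimated per group and a fit with each array's mean of the positive control probe sets as a covariate were chosen after seeing the data, as were the stricter filter and the 6-array fit for gene lists. The covariate's slope is set within groups, mostly by the 3 anti-PD-1/L1 arrays (SD 0.19, against 0.04 in the combination and 0.02 in anti-CD27). It is then carried over group differences of 1.06 and 0.95, so values with the covariate are not a full correction for array quality. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.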

Results

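Transcripts were measured on 9 arrays, 1 for each mouse, in transferred pmel1 CD8+ T cells recovered from the spleen on day 4 after peptide. CD27 is a costimulatory receptor of the TNF receptor family, and PD-1 with its ligand PD-L1 forms an inhibitory pathway of T cells. The 3 groups of 3 mice received antibodies to PD-1 and PD-L1 (anti-PD-1/L1), an agonist antibody to CD27 (anti-CD27), or all of these antibodies (the combination). Cd8a, which encodes a chain of the CD8 coreceptor used in the sort, had a mean log2 level of 10.53 ± 0.07 (SD, n = 3) in the combination, 10.77 ± 0.02 in anti-CD27 and 9.21 ± 0.37 in anti-PD-1/L1. Thy1, whose product was the other marker of the sort, was at 8.39 ± 0.02, 8.44 ± 0.07 and 7.41 ± 0.25. The probe set of Cd27, the receptor targeted by the agonist antibody, was at 9.98 ± 0.11, 9.91 ± 0.03 and 9.37 ± 0.34.

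The 3 anti-PD-1/L1 arrays differed from the other 6 in several kinds of control probe sets and in the spread of all genes. Bacterial and phage control probe sets had a mean of 9.75 ± 0.12 (SD, n = 3) on the anti-PD-1/L1 arrays, against 8.60 ± 0.02 for anti-CD27 and 8.60 ± 0.11 for the combination. Background control probe sets were at 4.06 ± 0.08, against 3.27 ± 0.06 and 3.25 ± 0.04, and positive control probe sets at 5.75 ± 0.19, against 6.70 ± 0.02 and 6.81 ± 0.04. The SD of all genes on an array was 2.04 ± 0.04 in anti-PD-1/L1, 2.22 ± 0.01 in anti-CD27 and 2.25 ± 0.01 in the combination. Each of these differences from anti-PD-1/L1 had an exact permutation p of 0.1, the smallest that 3 arrays against 3 can give. The first principal component held 85.6% of the variance of the genes. Because of the differences of the anti-PD-1/L1 arrays, the comparison of the combination with anti-CD27 is given first.

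**Figure D1:**
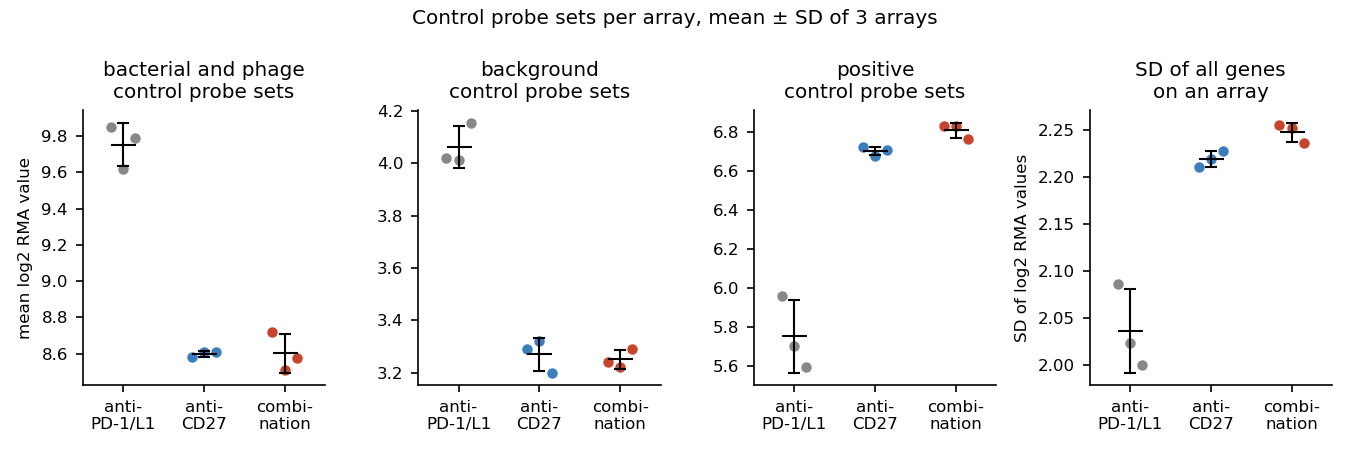
Control probe sets and the SD of all genes on each of the 9 arrays (y axes, log2 RMA values), with points for arrays and bars for the mean ± SD of 3 arrays. The anti-PD-1/L1 arrays lie above the other 6 for bacterial and phage controls (9.75 against 8.60) and below them for positive controls (5.75 against 6.70 and 6.81).

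The comparison of the combination with anti-CD27 asks what blockade of PD-1 and PD-L1 added to CD27 agonism. Cells from the combination had 26.8-fold more transcript of Gzmb, the serine protease granzyme B of cytotoxic granules, with a log2 level of 8.68 ± 0.31 (SD, n = 3) against 3.93 ± 0.44 (adjusted p = 0.00128). Il12rb2, the signalling chain of the interleukin-12 receptor, rose by at least 3.39 ± 0.07 (log2 difference ± SE, adjusted p = 3.68e-07), and Il2ra, the high-affinity chain of the interleukin-2 receptor, by at least 2.51 ± 0.11 (adjusted p = 5.84e-05). Both are given as lower limits, since their anti-CD27 levels of 3.28 and 3.05 were not clearly above the background controls of that group (3.27). Genes of DNA replication rose together, among them Mcm3, a subunit of the replicative helicase, by 2.46-fold (1.30 ± 0.09, adjusted p = 0.000685). St6gal1, which adds sialic acid to glycans, fell by 1.82 ± 0.13 on the log2 scale (adjusted p = 0.000685), and Itgae, the integrin chain CD103, fell by 1.56 ± 0.16 (adjusted p = 0.00305). The plot of single genes shows these levels on each array.

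**Figure D2:**
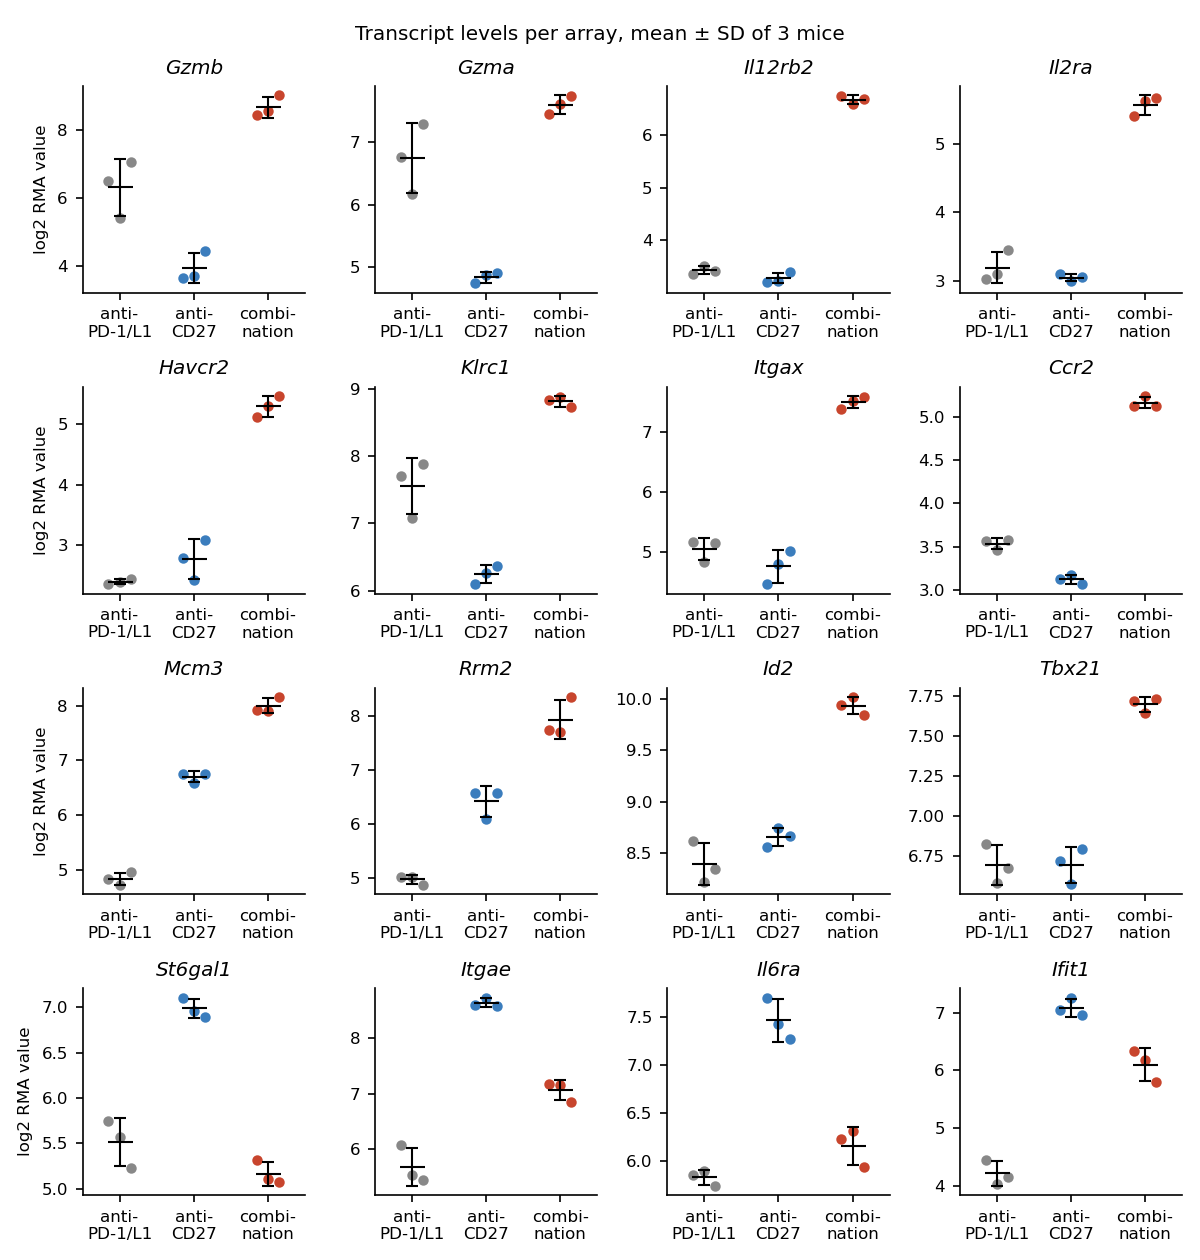
Levels of 16 named genes on each array (y axes, log2 RMA values) by treatment group, with points for mice and bars for the mean ± SD of 3 mice. Gzmb was at 8.68 in the combination, 6.31 in anti-PD-1/L1 and 3.93 in anti-CD27, and Il12rb2 at 6.67, 3.43 and 3.28.

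Among the other largest rises, Gzma, a further granzyme, rose by 2.78 ± 0.24, Itgax, the integrin chain CD11c, by 2.73 ± 0.14, and Klrc1, the inhibitory receptor NKG2A, by 2.56 ± 0.18. Havcr2, the inhibitory receptor TIM-3, rose by at least 2.51 ± 0.15, from 2.77 ± 0.33, below the background controls, to 5.29 ± 0.17. Ctla2b and Ctla2a, which encode cysteine protease inhibitors, rose by 2.23 ± 0.22 and 2.22 ± 0.13, and Plek, the protein kinase C substrate pleckstrin, by 2.22 ± 0.16. The highest adjusted p among these was 0.00237, for Ctla2b. Nrn1, which encodes neuritin, fell by 1.64 ± 0.14, the actin-associated gene Rflnb by 1.51 ± 0.20, and Rgs2, a regulator of G protein signalling, by 1.31 ± 0.12. Il6ra, a chain of the interleukin-6 receptor, fell by 1.31 ± 0.13, Slfn5, of the interferon-inducible Schlafen family, by 1.24 ± 0.14, and Izumo1r, a folate receptor of T cells, by 1.18 ± 0.14 (adjusted p = 0.00654). The small RNA gene Rn4.5s fell by 1.20 ± 0.19 (adjusted p = 0.0177), a call that was lost without replicate 1 or 2 of anti-CD27 or replicate 2 of the combination (adjusted p up to 0.0765). Ccr4, a chemokine receptor, differed by -1.19 ± 0.17 (adjusted p = 0.0125), at 2.22 ± 0.24 and 3.40 ± 0.31 not clearly above background in either group, and its call was lost without replicate 1 or 2 of anti-CD27 or replicate 2 or 3 of the combination (adjusted p up to 0.0679).

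Among 29 genes of DNA replication and S phase, 22 rose in the combination and 7 did not pass, and 27 rose when adjusted over the list alone. Rrm2, the small subunit of ribonucleotide reductase, rose 2.86-fold (1.52 ± 0.19), and Mcm5, of the same helicase as Mcm3, rose 2.42-fold (1.27 ± 0.16). The median of the list was 0.82, with a camera adjusted p of 7.14e-51 and an adjusted p = 0.0421 with an estimated correlation. Of 27 genes of G2/M and mitosis, 1 rose over all genes, Ccnb2, which encodes cyclin B2, by 1.49 ± 0.23 (adjusted p = 0.0175), and 26 did not pass. Without replicate 1 or 2 of anti-CD27, or any 1 of the combination arrays, Ccnb2 did not pass (adjusted p up to 0.0828). Adjusted over the list alone, 20 of the 27 rose, and the list's median was 0.87, with a camera adjusted p of 2.33e-20 and an adjusted p = 0.161 with an estimated correlation. Mki67, which encodes the proliferation marker Ki-67, differed by 1.08 ± 0.34 and did not pass (adjusted p = 0.252), with levels of 8.48 ± 0.55 and 7.40 ± 0.48. Positive control probe sets were 0.11 higher on the combination arrays than on the anti-CD27 arrays, with an exact permutation p of 0.1.

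Cytotoxic effector molecules rose in the combination in 5 of 18 measured genes, none fell and 13 did not pass, and 8 rose adjusted over the list alone. Besides Gzmb and Gzma, Serpinb9, an inhibitor of granzyme B that protects the cell holding it, rose 2.52-fold (1.33 ± 0.13, adjusted p = 0.00241). The list's median was 0.29, or 0.16 with the positive control covariate, with a camera adjusted p of 3.08e-12 and an adjusted p = 0.0421 with an estimated correlation. Prf1, the pore-forming perforin, differed by 0.19 ± 0.09 (adjusted p = 0.643) and Ifng, the cytokine interferon gamma, by 0.21 ± 0.28 (adjusted p = 1). Of 13 receptors of the NK type, 7 rose and 6 did not pass, and 8 rose adjusted over the list alone. Klrk1, the activating receptor NKG2D, rose by 1.91 ± 0.14, Klrc2 by 1.76 ± 0.13, and Klrg1, a receptor of differentiated effector cells, by at least 1.35 ± 0.15 (adjusted p = 0.00471) from a background level of 3.29. This list had a median of 0.61, a camera adjusted p of 5.79e-13 and an adjusted p = 0.0421 with an estimated correlation. Among 15 effector transcription factors, 5 rose and 10 did not pass, and adjusted over the list alone 5 rose and 1 fell. Id2 rose by 1.29 ± 0.10, Eomes by 1.10 ± 0.14, and Tbx21, which encodes T-bet, by 1.00 ± 0.08 (adjusted p = 0.00103). The median of the factors was 0.16, with a camera adjusted p of 7.19e-07 and an adjusted p = 0.0644 with an estimated correlation. Markers of NK cells did not move with these genes, with a median of -0.01 over 7 genes.

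Inhibitory receptors moved both ways, with 3 of 16 higher, 3 lower and 10 not past the threshold, and with 4 up and 3 down adjusted over the list alone. Beside Havcr2, Lilrb4a rose by 1.58 ± 0.16 (adjusted p = 0.00336), while Ctla4, a competitor of the costimulatory receptor CD28, fell by 0.67 ± 0.09 (adjusted p = 0.00771). Cd274, which encodes PD-L1, fell by 0.64 ± 0.12 (adjusted p = 0.0406), and its call was lost without any 1 of the 6 arrays compared or replicate 3 of anti-PD-1/L1 (adjusted p up to 0.169). Pdcd1, which encodes PD-1, differed by 0.31 ± 0.07 and did not pass (adjusted p = 0.0926), though it did without replicate 1 or 2 of anti-PD-1/L1 and with the 6 arrays alone (adjusted p = 0.0161). The list was not shifted (camera adjusted p = 0.93), and its median of -0.07 and mean of 0.18 differed in sign. Of 18 costimulatory receptors and ligands, 1 rose, Cd80, by 2.82-fold (adjusted p = 0.00207), and adjusted over the list alone 3 rose and 2 fell (median 0.08, camera adjusted p = 0.2). The Cd27 probe set differed by 0.08 ± 0.15 (adjusted p = 1 over all probe sets). Among 25 cytokine receptors and STAT feedback genes, 3 rose, 3 fell and 19 did not pass, and 4 rose and 4 fell adjusted over the list alone. Il12rb2 and Il2ra rose and Il6ra fell, as given above, while Il7r, the interleukin-7 receptor chain of long-lived cells, differed by 0.11 ± 0.17 (adjusted p = 1). This list was not shifted (camera adjusted p = 0.994), with a median of -0.03, a mean of 0.18 and a test direction that was down.

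None of 18 cytokines and chemokines passed, and the largest difference was 0.42 ± 0.19 in Ccl5, a chemokine of effector cells (adjusted p = 0.537). Adjusted over the list alone, 1 of them fell, and the list was not shifted (median -0.01, mean 0.00, camera adjusted p = 0.354). Of 24 chemokine receptors and adhesion genes, 5 rose, 2 fell and 17 did not pass, and 6 rose and 2 fell adjusted over the list alone. Ccr2, a receptor for inflammatory chemokines, rose by at least 2.04 ± 0.06 (adjusted p = 2.34e-06) from 3.12, below the background controls, beside the rise of Itgax and the fall of Itgae. The median of this list was 0.07 (0.01 after quantile normalization) with a camera adjusted p of 0.00573, and the call was lost with an adjusted p = 0.286 with an estimated correlation. It was also lost with the 6 arrays alone (adjusted p = 0.069) and with the positive control covariate (adjusted p = 0.466).

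Of 16 genes associated with naive and memory cells, 3 fell in the combination and 13 did not pass, and 10 fell and 2 rose adjusted over the list alone. Besides Il6ra, Dapl1 fell by 0.78 ± 0.11 (adjusted p = 0.00926) and Lef1, a transcription factor of naive T cells, by 0.63 ± 0.11 (adjusted p = 0.028). Dapl1 did not pass without replicate 1 or 2 of anti-CD27 or replicate 2 of the combination (adjusted p up to 0.0536), and Lef1 did not pass without any 1 of the 6 arrays compared (adjusted p up to 0.144). The list's median was -0.29, with a camera adjusted p of 1.38e-08 and an adjusted p = 0.174 with an estimated correlation. In the type I interferon response, 5 of 26 genes fell and 21 did not pass, and 12 fell and 1 rose adjusted over the list alone. Ifit3, an interferon-induced gene, fell by 0.73 ± 0.07 (adjusted p = 0.00216) and Ifit1 by 0.99 ± 0.16 (adjusted p = 0.0181), of which Ifit1 did not pass without replicate 1 or 2 of anti-CD27 or replicate 2 of the combination (adjusted p up to 0.0898). Their list had a median of -0.25, a camera adjusted p of 1.99e-13 and an adjusted p = 0.0872 with an estimated correlation.

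Of 19 genes of the NF-kB pathway and its targets, 3 fell and 16 did not pass, and 7 fell adjusted over the list alone. Tnfaip3, a feedback inhibitor of the pathway, fell by 1.05 ± 0.18 (adjusted p = 0.0238), and did not pass without replicate 1 or 2 of anti-CD27 or replicate 1 or 3 of the combination (adjusted p up to 0.124). The median was -0.21, with a camera adjusted p of 2.05e-09 and an adjusted p = 0.0906 with an estimated correlation. Among 19 immediate early genes of the T cell receptor, 2 fell and 17 did not pass, and 4 fell adjusted over the list alone. Both were phosphatases that act on MAP kinases, Dusp1 by -0.94 ± 0.16 (adjusted p = 0.0253) and Dusp2 by -0.83 ± 0.12 (adjusted p = 0.0104). Dusp1 was lost without replicate 1 or 2 of anti-CD27 or any 1 combination array (adjusted p up to 0.13), and Dusp2 without replicate 1 or 2 of anti-CD27 or replicate 2 or 3 of the combination (adjusted p up to 0.0629). Their list had a median of -0.18, a camera adjusted p of 3.7e-05 and an adjusted p = 0.204 with an estimated correlation. The BCL2 family and survival kinases were not shifted (median 0.00, mean -0.02, camera adjusted p = 0.93), and the only 1 of 17 that passed, Bcl2l11, which encodes the death-promoting BIM, fell by 0.42 ± 0.07 (adjusted p = 0.0252). Its call was lost without replicate 2 or 3 of anti-CD27 or any 1 combination array (adjusted p up to 0.104).

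Of 22 genes of Myc and ribosome biogenesis, 2 rose and 20 did not pass, and 7 rose adjusted over the list alone (median 0.20, quantile 0.13, camera adjusted p = 1.23e-08). This call was kept with an adjusted p = 0.0462 with an estimated correlation. Nolc1, a nucleolar protein, rose by 0.35 ± 0.04 (adjusted p = 0.00655), and Myc itself differed by 0.22 ± 0.09 (adjusted p = 0.415). In glycolysis, 2 of 15 rose, and 7 rose and 1 fell adjusted over the list alone (median 0.22, camera adjusted p = 1.11e-07, adjusted p = 0.148 with an estimated correlation). Tpi1, a glycolytic isomerase, rose by 0.63 ± 0.10 (adjusted p = 0.0171) and did not pass without any 1 of the anti-CD27 arrays or replicate 2 of the combination (adjusted p up to 0.0905). In oxidative phosphorylation, 1 of 25 rose, and 5 rose adjusted over the list alone (median 0.19, or 0.10 with the positive control covariate and 0.09 after quantile normalization, camera adjusted p = 4.48e-09, adjusted p = 0.154 with an estimated correlation). That gene was Ndufa9, of respiratory complex I (0.34 ± 0.05, adjusted p = 0.0142), which was lost without any 1 of the anti-CD27 arrays or replicate 1 or 3 of the combination (adjusted p up to 0.0787) and after quantile normalization (adjusted p = 0.155). In cholesterol synthesis, 3 of 16 rose, and 8 rose adjusted over the list alone (median 0.18, camera adjusted p = 1.88e-07, adjusted p = 0.174 with an estimated correlation). Fdps, a synthase of the mevalonate pathway, rose by 0.72 ± 0.11 (adjusted p = 0.0153), and not without replicate 1 of anti-CD27 or any 1 combination array (adjusted p up to 0.0836).

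In the unfolded protein response and amino acid stress, 5 of 20 genes rose and 15 did not pass, and 8 rose and 2 fell adjusted over the list alone. Slc7a5, an amino acid transporter of activated T cells, rose by 0.73 ± 0.09 (adjusted p = 0.00753). The list's median was 0.15, or 0.09 with the positive control covariate and 0.06 after quantile normalization, with a camera adjusted p of 0.000916 and an adjusted p = 0.151 with an estimated correlation. In the heat shock list, 1 of 9 rose, Hsph1, a chaperone, by 0.72 ± 0.14 (adjusted p = 0.0439), and 2 rose adjusted over the list alone. Hsph1 did not pass without any 1 anti-CD27 array, replicate 1 or 2 of the combination or replicate 2 or 3 of anti-PD-1/L1 (adjusted p up to 0.178), nor after quantile normalization (adjusted p = 0.0791) or with the positive control covariate (adjusted p = 0.0646). This list had a median of 0.09 (0.03 after quantile normalization, percentile 91.7 among random lists of like level) and a camera adjusted p of 0.00651, which was lost with an adjusted p = 0.0906 with an estimated correlation and with the positive control covariate (adjusted p = 0.12) or without the 50% of genes with the lowest means (adjusted p = 0.0509). No gene of 15 p53 targets passed, and the list was not shifted (median 0.01, camera adjusted p = 0.994), with Gtse1 differing most, by 0.53 ± 0.23 (adjusted p = 0.524).

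Markers of other cells showed little difference between the combination and anti-CD27. The list of 5 CD4 T cell markers was shifted down (median -0.17, camera adjusted p = 8.56e-05, adjusted p = 0.0421 with an estimated correlation), with 2 past the threshold over all genes and 3 adjusted over the list alone. St8sia6 fell by at least 0.57 ± 0.10 to 3.07, below the background controls (adjusted p = 0.0257), and Ikzf2, which encodes the factor Helios, by 0.37 ± 0.07 (adjusted p = 0.0413). Both calls were lost without replicate 1 or 2 of anti-CD27 or any 1 combination array, and that of Ikzf2 also without replicate 3 of anti-CD27 (adjusted p up to 0.125 and 0.151). In the dendritic cell list Itgax alone passed, a gene that effector T cells also express, and the list was not shifted (median 0.00, mean 0.24, camera adjusted p = 0.275). No member of the B cell, monocyte and macrophage, neutrophil, platelet and megakaryocyte or NK cell lists passed, and none of these lists was shifted (lowest camera adjusted p 0.717). Their largest differences were -0.49 ± 0.15 in Ighm, 0.36 ± 0.12 in Cd68, 0.11 ± 0.08 in Ly6g, -0.11 ± 0.10 in Gp9 and 0.30 ± 0.15 in Cd7. The erythroid markers had a median of -0.01 over 4 genes, with -0.04 ± 0.07 in Slc4a1. Cd8a differed by -0.24 ± 0.15 (adjusted p = 0.841) and Thy1 by -0.05 ± 0.11 (adjusted p = 1).

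**Figure D3:**
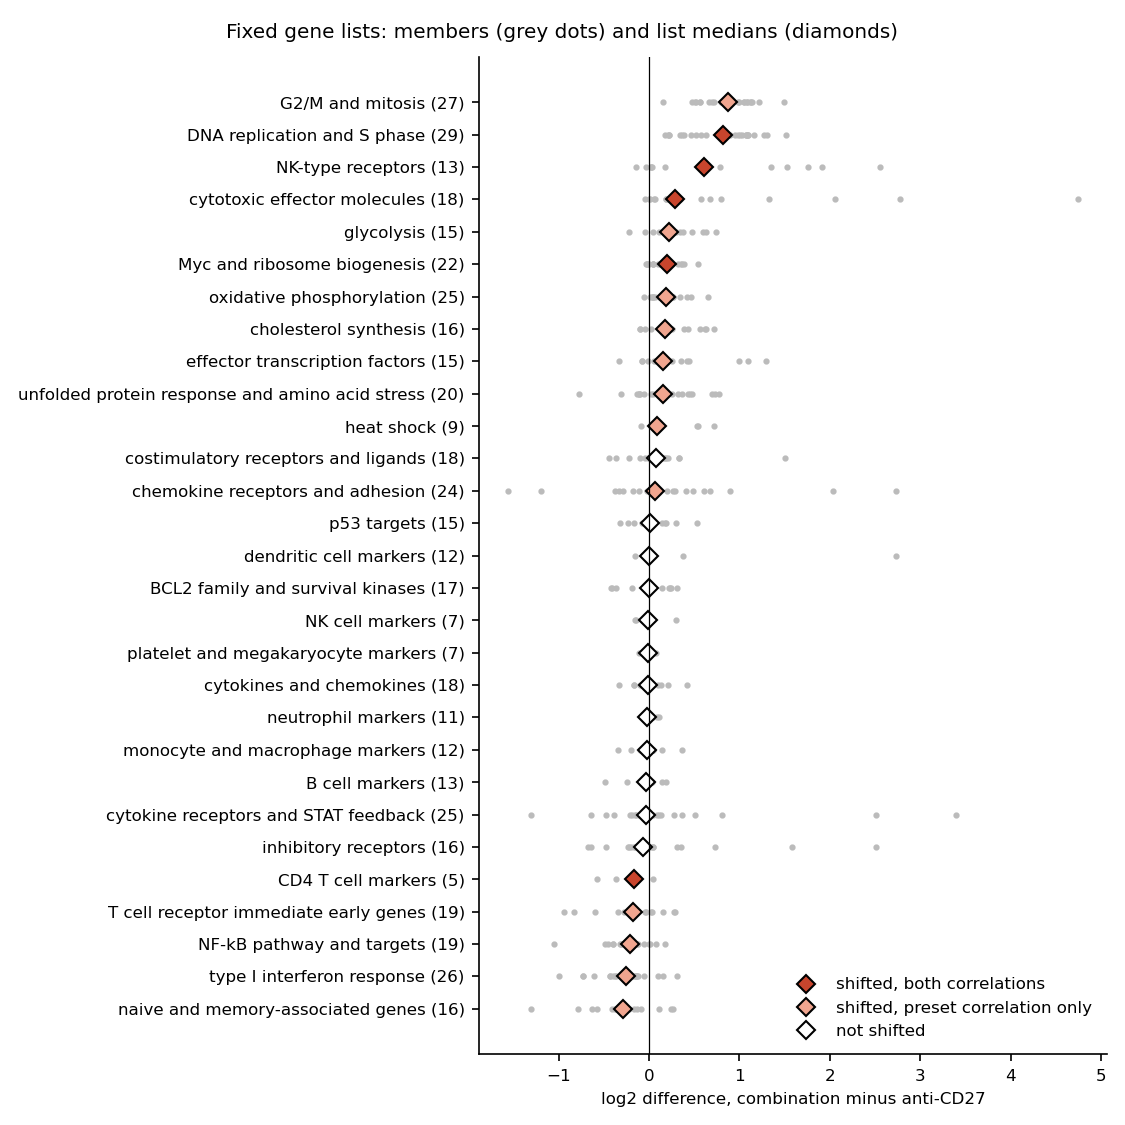
Differences of the fixed gene lists between the combination and anti-CD27 (x axis, log2 difference), with grey dots for measured genes, diamonds for list medians and numbers of measured genes in brackets. Filled diamonds mark lists shifted by camera with both correlations (dark) or with the preset correlation alone (pale), and the medians of the S phase and NK-type receptor lists were 0.82 and 0.61.

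In the combination against anti-CD27, limma called 546 of 30632 genes (1.78%), of which 386 rose and 160 fell, and 2965 had an unadjusted p under 0.05. Of the calls, 84 were at least 2-fold, 71 up and 13 down, and all 546 had no overlap between the arrays of both groups, where chance gives 10% of genes not selected by their p. The split was 424 up and 122 down with centred arrays and 331 and 216 after quantile normalization. Camera called 17 of 29 lists, 12 up and 5 down, and 5 of them, 4 up and 1 down, with an estimated correlation. The count of genes depended on single arrays: it was 174, 183 and 293 without replicates 1, 2 and 3 of anti-CD27, 257, 208 and 275 without replicates 1, 2 and 3 of the combination, and 1218 without replicate 1 of anti-PD-1/L1, with 152 genes called in every one of the 9 fits. With the 6 arrays of the comparison alone, which leaves the anti-PD-1/L1 arrays out, 1645 genes were called and 496 of the 546 were kept.

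The comparison of the combination with anti-PD-1/L1 asks what CD27 agonism added to blockade. Mki67 rose in the combination by at least 3.98 ± 0.34 (adjusted p = 1.89e-05), and Kif11, a mitotic kinesin, rose by at least 4.03 ± 0.32 (adjusted p = 1.14e-05). Il12rb2 rose by at least 3.24 ± 0.07 (adjusted p = 2.35e-08), Havcr2 by at least 2.88 ± 0.15 and Il2ra by at least 2.37 ± 0.11. Kif11, Il12rb2, Havcr2 and Il2ra were at 3.83, 3.43, 2.40 and 3.19 in anti-PD-1/L1, below its background controls (4.06), and Mki67 was within 1 SD of them. Against anti-PD-1/L1, a rise of "at least" a value is limited by background alone and does not allow for the array differences. With the positive control covariate Lilrb4a and Cd80, given below, were under such limits, at 3.3 and 1.61. Il12rb2, Havcr2, Il2ra, Smc3 and Klrg1 were above theirs, at 3.47, 3.1, 3.44, 5 and 1.58. Gzmb rose 5.14-fold (2.36 ± 0.39, adjusted p = 0.000683). Il7r, the interleukin-7 receptor chain, rose 6.83-fold (2.77 ± 0.17). The median of all genes was -0.26, and centring the arrays on their medians adds 0.38 to each difference, so that Mki67 was 4.36 and Gzmb 2.74 higher relative to the array median. These rises went with the 1.15 lower bacterial and phage controls and the 1.06 higher positive controls of the combination arrays.

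The largest rise was in Cbl, an E3 ubiquitin ligase that limits T cell receptor signalling, from 4.67 ± 0.94, not clearly above background, to 9.30 ± 0.12 (at least 4.63 ± 0.38). Eif3a and Eif3c, subunits of a translation initiation factor, rose by 4.05 ± 0.07 and 3.81 ± 0.19, and Gbp7, an interferon-inducible GTPase, by 4.04 ± 0.10. Smc3, a subunit of cohesin, rose by at least 3.95 ± 0.10 from a background level of 4.04, Actn1, which encodes an actinin, by 3.84 ± 0.08, Ddx21, a nucleolar helicase, by 3.81 ± 0.12, and Iqgap1, a scaffold of the cytoskeleton, by 3.81 ± 0.07. All 10 of the largest falls were small structured RNAs. The spliceosomal RNA Rnu2-10 fell by 2.37 ± 0.25, Rnu12 by 1.79 ± 0.19 and Rnu5g by at least 1.77 ± 0.20 to 3.17, below the background controls (3.25). Rny1 and Rny3, which encode Y RNAs, fell by 2.08 ± 0.19 and 2.00 ± 0.19, and the Cajal body RNAs Scarna6 and Scarna10 by 1.99 ± 0.28 and 1.83 ± 0.17. Scarna8 differed by -1.85 ± 0.32, at 4.32 ± 0.79 and 2.47 ± 0.07 not clearly above background in either group. The small nucleolar RNA AF357399, at 4.06 and 1.74 not above background in either group, differed by -2.33 ± 0.43, and the ribosomal RNA Rn5s fell by 2.21 ± 0.31, and both differences turned positive with the positive control covariate, to 0.74 (adjusted p = 0.856) and 0.15 (adjusted p = 0.963). Over 94 genes of small structured RNAs the median was -0.96, with -0.58 for centred arrays and -1.21 after quantile normalization.

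Of 29 S phase genes 25 rose and 4 did not pass, and 25 rose and 1 fell adjusted over the list alone (median 0.97, and 1.35 with centred arrays). Mcm6 rose by 3.23 ± 0.09 and Mcm3 by 3.17 ± 0.09. Of 27 G2/M and mitosis genes 23 rose and 4 did not pass, and 26 rose adjusted over the list alone (median 1.88, centred 2.26). Camera gave adjusted p of 1.81e-14 and 1.77e-12 for these lists, and both calls were lost, with adjusted p = 0.131 and 0.24 with an estimated correlation. Both were kept with the positive control covariate, with medians of 1.01 and 2.59 (adjusted p = 1.69e-08 and 3.69e-06).

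Among 18 cytotoxic effector molecules, 10 rose, 3 fell and 5 did not pass, with the same counts adjusted over the list alone (median 0.46, centred 0.84, camera adjusted p = 0.000852). Ifng rose 2.83-fold (adjusted p = 0.00136), and with the positive control covariate it was at -1.03 (adjusted p = 0.615). Prf1 rose by 0.52 ± 0.09 (adjusted p = 0.00101), a call lost after quantile normalization (0.13, adjusted p = 0.209), and it was at -0.14 with the covariate. In the NK-type receptors, 6 of 13 rose and 3 fell, over all genes and over the list alone (median 0.07, centred 0.45, quantile 0.47, camera adjusted p = 0.00919), with Klrk1 up by 1.51 ± 0.14 and Klrg1 by at least 0.58 ± 0.15 from a background level of 4.07. Of 15 effector transcription factors, 10 rose and 2 fell, and 10 rose and 3 fell adjusted over the list alone (median 1.00, camera adjusted p = 9.43e-06). Stat4, which signals from the interleukin-12 receptor, rose by 3.09 ± 0.17, Eomes by 1.72 ± 0.14 and Tbx21 by 1.00 ± 0.08. All 3 list calls were lost, with adjusted p = 0.131 for cytotoxic molecules and transcription factors and adjusted p = 0.24 for NK-type receptors with an estimated correlation. They were also lost with the covariate, where the medians were 0.15, 0.43 and 0.21 in that order (adjusted p = 0.551, 0.0938 and 0.376).

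In the inhibitory receptors, 11 of 16 rose and 2 fell (median 0.41, centred 0.79, quantile 0.26, camera adjusted p = 2.88e-05), with Lilrb4a up by at least 3.76 ± 0.16 from 3.05, below the background controls. Cd274 rose by 1.20 ± 0.12 (adjusted p = 4.14e-05) and was at -0.01 with the positive control covariate. Pdcd1 rose by 0.21 ± 0.07 (adjusted p = 0.0294), but was at -0.27 after quantile normalization (adjusted p = 0.00721) and at -0.13 with the covariate, and it did not pass without replicate 2 of anti-PD-1/L1 or replicate 2 or 3 of the combination (adjusted p up to 0.0897). Of 18 costimulatory receptors and ligands, 12 rose and 4 fell (median 0.43, centred 0.81, camera adjusted p = 0.000141), with Cd80 up by at least 2.40 ± 0.14 from 3.42, also below them, and Slamf1 by 2.13 ± 0.09. The Cd27 probe set was higher by 0.61 ± 0.15 (adjusted p = 0.00608 over all probe sets). In the cytokine receptors and STAT feedback genes, 18 of 25 rose and 4 fell (median 1.26, centred 1.64, quantile 0.80, camera adjusted p = 2.63e-08), among them Jak1, a kinase of cytokine receptors, by 3.01 ± 0.08. In the chemokine receptors and adhesion genes, 13 of 24 rose and 3 fell (median 0.53, centred 0.91, camera adjusted p = 1.47e-05), with the integrin chains Itgal and Itga4 up by 2.95 ± 0.12 and 2.67 ± 0.09. The counts of these lists were the same adjusted over the list alone, and every call was lost, with adjusted p from 0.13 to 0.131 with an estimated correlation. The medians of the inhibitory, costimulatory and chemokine receptor lists with the positive control covariate turned to -0.11, -0.24 and -0.02, that of the cytokine receptors was 0.12, and none was called (adjusted p = 0.774, 0.895, 0.774 and 0.0684). Of 18 cytokines and chemokines, 5 rose and 7 fell over all genes and over the list alone, with Tgfb1 up by 2.16 ± 0.06. That list was not shifted (camera adjusted p = 0.209), and its median of -0.16 lay below 0 while its mean was 0.21, its test direction was up and its centred median was 0.22.

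Naive and memory-associated genes rose in 11 of 16 and fell in 2, and 11 rose and 3 fell adjusted over the list alone (median 0.70, centred 1.08, camera adjusted p = 1.73e-05). Random lists of genes of like level had a median of 0.25, and the list stood at percentile 92.3 among them. The type I interferon response rose in 21 of 26 and fell in 3, over all genes and over the list alone (median 0.54, centred 0.92, camera adjusted p = 5.25e-09), with Ddx58, the RNA sensor RIG-I, up by 2.52 ± 0.08 and the RNA sensor Ifih1 up by at least 2.37 ± 0.13 from 3.43, below the background controls. In the NF-kB list 17 of 19 rose and none fell, over all genes and over the list alone (median 1.18, centred 1.56, camera adjusted p = 2.83e-12), with Rela, a subunit of NF-kB, up by 2.56 ± 0.09. Of 19 immediate early genes 10 rose and 3 fell, over all genes and over the list alone (median 0.33, centred 0.71, camera adjusted p = 0.000274), with the activation marker Cd69 up by 1.79 ± 0.18 and a list median of -0.05 after quantile normalization. Random lists of like level had a median of 0.31, and the immediate early list stood at percentile 55 among them. All 4 calls were lost, with adjusted p of 0.24, 0.131, 0.13 and 0.24 in that order with an estimated correlation. Medians with the positive control covariate were in that order -0.02, -0.12, 0.77 and 0.35, and the NF-kB list alone was called (adjusted p = 0.000317, the others 0.895, 0.523 and 0.331).

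Myc and ribosome biogenesis rose in 18 of 22 and fell in 3 (median 0.72, centred 1.10, quantile 0.45, camera adjusted p = 4.55e-09), with nucleolin, Ncl, up by 3.09 ± 0.10 and Myc up by 0.89 ± 0.09. Glycolysis rose in 11 of 15 and fell in 2 (median 0.53, centred 0.91, quantile 0.16, camera adjusted p = 1.71e-05), with Pfkp up by 1.72 ± 0.09. Oxidative phosphorylation rose in 10 of 25 and fell in 7 (median 0.10, centred 0.48, camera adjusted p = 0.0171), and its median turned to -0.21 after quantile normalization. With the positive control covariate the list was shifted down (median -0.58, adjusted p = 0.0461). Sdha and Cycs, of the respiratory chain, rose by 1.37 ± 0.16 and 1.15 ± 0.17 and were at -0.50 and -0.78 with the positive control covariate. Cholesterol synthesis rose in 11 of 16 and fell in 1, and 12 rose and 1 fell adjusted over the list alone (median 0.45, centred 0.83, quantile 0.27, camera adjusted p = 1.79e-05). Its member Hmgcs1 rose by 1.90 ± 0.18 and was at -0.40 with the covariate. For the other lists of this paragraph the counts were the same adjusted over the list alone. These calls were lost, with adjusted p from 0.13 to 0.482 with an estimated correlation. Among random lists of like level, glycolysis, oxidative phosphorylation and cholesterol synthesis stood at percentiles 80.4, 9.62 and 90.7, and the random medians were 0.27, 0.41 and 0.11, that for oxidative phosphorylation being above its own median of 0.10. With the covariate the medians of the Myc, glycolysis and cholesterol lists were 0.29, 0.05 and -0.30, and of these the Myc list was called (adjusted p = 0.007, the others 0.444 and 0.774).

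The unfolded protein response and amino acid stress list rose in 12 of 20 and fell in 5 (median 0.27, centred 0.65, quantile -0.11, camera adjusted p = 0.00153), with the chaperone Hsp90b1 up by 3.21 ± 0.11. The BCL2 family and survival kinases rose in 8 of 17 and fell in 5 (median 0.24, centred 0.62, quantile 0.08, camera adjusted p = 0.0171), with Bcl2l11 up 2.82-fold. Adjusted over the list alone the counts of both were the same, and both calls were lost, with adjusted p = 0.16 and 0.131 with an estimated correlation. They stood at percentiles 69.8 and 70.5 among random lists of like level, whose medians were 0.14 and 0.11. Their medians turned with the positive control covariate to -0.19 and -0.21 (adjusted p = 0.829 and 0.895). Heat shock genes, 4 of 9 higher and 3 lower, or 4 and 4 adjusted over the list alone, were not shifted (camera adjusted p = 0.0714), with a median of -0.05, a mean of 0.71, a test direction that was up and a centred median of 0.33. Of 15 p53 targets 5 rose and 7 fell, over all genes and over the list alone. They were not shifted (camera adjusted p = 0.773), with a median of -0.20, a mean of -0.03, a test direction that was up and a centred median of 0.18. Trp53inp1 rose by 0.92 ± 0.14 and was at -0.81 with the covariate, and Bbc3, which encodes the death-promoting PUMA, fell by 0.84 ± 0.06.

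Markers of other cells were mostly lower in the combination than in anti-PD-1/L1 as deposited and near 0 relative to the array median. Over all genes, 8 of 13 B cell, 9 of 12 monocyte and macrophage, 8 of 11 neutrophil, 9 of 12 dendritic cell, 5 of 7 platelet, 3 of 5 CD4 T cell and 4 of 7 NK cell markers fell, and 2, 1, 0, 2, 1, 1 and 1 rose, with the same counts adjusted over each list alone. Their medians were -0.36, -0.44, -0.53, -0.26, -0.34, -0.20 and -0.22 as deposited and 0.02, -0.06, -0.15, 0.12, 0.04, 0.18 and 0.16 with centred arrays. All 4 erythroid markers fell, with a median of -0.40, and -0.02 with centred arrays. Camera called none of the 7 lists (lowest adjusted p 0.13). The mean of the dendritic list was 0.02 and that of the CD4 list 0.10, opposite in sign to their medians, and the test direction of the CD4 list was up. Cd79a, a B cell receptor chain, fell by 0.88 ± 0.09, from 3.92 ± 0.17, below the background controls, and was at 0.08 with the positive control covariate. Cd68, Bst2 and Cd7 rose by 0.77 ± 0.12, 0.78 ± 0.23 and 0.91 ± 0.15 and were at -0.46, -1.81 and -0.85 with it. The call of Bst2 was lost without replicate 3 of anti-PD-1/L1 or replicate 2 of the combination (adjusted p up to 0.0517). The markers of the sort moved too: Cd8a rose by 1.32 ± 0.15 and Thy1 by 0.98 ± 0.11, and with the covariate they were at -0.70 and -0.39.

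In total 22140 of 30632 genes were called between the combination and anti-PD-1/L1 (72.3%), 5813 up and 16327 down, and 23004 had an unadjusted p under 0.05. The split was 12272 up and 5320 down with centred arrays and 7351 and 8541 after quantile normalization. Of the calls, 3348 were at least 2-fold, 2279 up and 1069 down, and 21166 had no overlap between arrays, where chance gives 10% of genes not selected by their p. Camera called 19 of 29 lists, all up, and 0 with an estimated correlation, while fry called 28, 21 up and 7 down. With the positive control mean of each array as a covariate 1910 genes were called, while the median size of the differences called in the main test went from 0.535 to 0.492, the median SE from 0.0855 to 0.338, and 65.1% of them kept their sign.

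Anti-CD27 was compared with anti-PD-1/L1 to ask how the 2 single treatments differed. Gzmb was 5.22-fold higher in anti-PD-1/L1 and fell by 2.38 ± 0.39 on the log2 scale (adjusted p = 0.000685), and Gzma, a further granzyme, fell by 1.91 ± 0.24 (adjusted p = 0.000136). The chemokine receptor Cxcr6 fell by 1.99 ± 0.20 (adjusted p = 4.08e-05), from 6.75 ± 0.36 (SD, n = 3) to 4.76 ± 0.27. Mki67 rose by at least 2.90 ± 0.34 (adjusted p = 0.000109), Il7r 6.31-fold (2.66 ± 0.17), and Ifit1, an interferon-induced gene, by at least 2.88 ± 0.16 (adjusted p = 1.48e-06). In anti-PD-1/L1, Ifit1 at 4.21 ± 0.21 and Mki67, within 1 SD, were not clearly above the background controls (4.06 ± 0.08). The median of all genes was again -0.26, and centring adds 0.36, so that Gzmb was at -2.02 and Mki67 at 3.27 relative to the array median. These differences went with the 1.15 lower bacterial and phage controls and the 0.95 higher positive controls of the anti-CD27 arrays.

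Several of the largest rises were in genes that also led the combination's rises. Cbl rose by at least 4.57 ± 0.38, Actn1 by 3.97 ± 0.08, Gbp7 by 3.91 ± 0.10, Eif3a by 3.72 ± 0.07, Iqgap1 by 3.62 ± 0.07 and Eif3c by 3.48 ± 0.19. Rnf213, a large ubiquitin ligase, rose by 4.06 ± 0.11, Prpf8, a core protein of the spliceosome, by 3.61 ± 0.06, Prrc2c by 3.51 ± 0.08 and Crebbp, a histone acetyltransferase, by 3.47 ± 0.10. The protease inhibitor genes Ctla2b and Ctla2a fell by 2.48 ± 0.22 and 2.27 ± 0.13. Rnu2-10 fell by 2.23 ± 0.25, Rny1 by 2.10 ± 0.19 and Scarna6 by 1.78 ± 0.28. AF357399, not above background in either group, and Rn5s differed by -2.27 ± 0.43 and -2.03 ± 0.31 and were at 0.50 (adjusted p = 0.896) and 0.10 (adjusted p = 0.972) with the positive control covariate. Of the 94 small structured RNAs 71 fell and 2 rose, with a median of -0.92, and of -0.55 with centred arrays and -1.07 after quantile normalization.

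Of 29 S phase genes 14 rose, 4 fell and 11 did not pass, over all genes and over the list alone (median 0.30, centred 0.67, quantile 0.19, percentile 93.6 among random lists of like level), with Mcm6 up by 2.14 ± 0.09 and Mcm4 by 1.90 ± 0.10. Of 27 G2/M and mitosis genes 16 rose and none fell, by both adjustments (median 0.94, centred 1.31), with Kif11 up by at least 3.04 ± 0.32 from 3.83, below the background controls. Camera gave adjusted p of 9.18e-06 and 5.03e-08, and both calls were lost, with adjusted p = 0.328 and 0.382 with an estimated correlation. Both were kept with the positive control covariate, with medians of 0.22 and 1.63 (adjusted p = 0.00704 and 0.00102). Cytotoxic effector molecules went both ways, with 6 of 18 higher and 10 lower by both adjustments. They were not shifted (camera adjusted p = 0.522), with a median of -0.33, a mean of -0.32, a test direction that was up, a centred median of 0.04 and a median of -0.14 after quantile normalization. Prf1 rose by 0.33 ± 0.09 (adjusted p = 0.011), was at 0.01 after quantile normalization (adjusted p = 0.939) and at -0.26 with the covariate. Ifng rose by 1.28 ± 0.28 and was at -0.99 with the covariate. In the NK-type receptors 11 of 13 fell and none rose, by both adjustments, and the list was not shifted (median -0.29, centred 0.07, camera adjusted p = 0.351). Klrc1 fell by 1.31 ± 0.18, Klrd1, which encodes CD94, by 0.78 ± 0.09, and Klrg1 by 0.77 ± 0.15, of which Klrg1 lay near background in both groups (3.29 and 4.07) and was at 0.12 with the covariate (adjusted p = 0.931).

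Effector transcription factors rose in 8 of 15 and fell in 4, by both adjustments (median 0.26, centred 0.63, quantile 0.45, percentile 84.2 among random lists of like level, camera adjusted p = 0.000287), with Bhlhe40 up by 3.05 ± 0.17, Stat4 by 2.67 ± 0.17 and Eomes by 0.61 ± 0.14. Tbx21 differed by 0.00 ± 0.08 (adjusted p = 0.993), by 0.37 with centred arrays and by -0.41 after quantile normalization (adjusted p = 0.00101). Inhibitory receptors rose in 9 of 16 and fell in 1 (median 0.41, centred 0.78, camera adjusted p = 4.39e-05), with Lilrb4a up by at least 2.19 ± 0.16 from 3.05, below the background controls, and Cd274 by 1.84 ± 0.12. Pdcd1 differed by -0.10 ± 0.07 (adjusted p = 0.249), by 0.27 with centred arrays (adjusted p = 0.017) and by -0.49 after quantile normalization (adjusted p = 0.000223), and it passed without replicate 2 of anti-PD-1/L1. Costimulatory receptors and ligands rose in 10 of 18 and fell in 2 (median 0.29, centred 0.65, camera adjusted p = 7.03e-05), with Slamf1 up by 1.80 ± 0.09 and the TNF receptor Tnfrsf1b by 1.60 ± 0.09. The Cd27 probe set was higher by 0.53 ± 0.15 (adjusted p = 0.012 over all probe sets). Cytokine receptors and STAT feedback genes rose in 15 of 25 and fell in 3 (median 0.81, centred 1.18, quantile 0.41, camera adjusted p = 1.07e-07), with Jak1 up by 2.97 ± 0.08, while Il2ra differed by -0.14 ± 0.11 (adjusted p = 0.288), by 0.22 with centred arrays and by 0.25 after quantile normalization. Chemokine receptors and adhesion genes rose in 10 of 24 and fell in 7 (median 0.15, centred 0.52, quantile 0.23, camera adjusted p = 0.00212), with Itgal up by 2.95 ± 0.12 and Itgae by 2.94 ± 0.16. Counts were the same adjusted over each list alone, and these calls were lost, with adjusted p from 0.109 to 0.27 with an estimated correlation. With the covariate the medians of the transcription factor, inhibitory, costimulatory and chemokine receptor lists turned to -0.13, -0.07, -0.14 and -0.21 and were not called (adjusted p = 0.467, 0.528, 0.957 and 0.957), and that of the cytokine receptors was 0.24 (adjusted p = 0.0236). Cytokines and chemokines rose in 5 of 18 and fell in 7 by both adjustments and were not shifted (camera adjusted p = 0.111), with a median of -0.07, a mean of 0.21, a test direction that was up and a centred median of 0.29, and Tgfb1 rose by 2.14 ± 0.06.

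Naive and memory-associated genes rose in 12 of 16 and fell in 2, and 13 rose and 2 fell adjusted over the list alone (median 0.96, centred 1.33, camera adjusted p = 1.53e-08), with Foxo1, a factor that maintains Il7r, up by 2.85 ± 0.18. The type I interferon response rose in 20 of 26 and fell in 1 (median 0.96, centred 1.32, camera adjusted p = 7.5e-13), with Ddx58 up by 2.64 ± 0.08. In the NF-kB list 17 of 19 rose and none fell, and 18 rose adjusted over the list alone (median 1.34, centred 1.71, camera adjusted p = 5.46e-15), with Tnfaip3 up by 3.09 ± 0.18 and Rela by 2.48 ± 0.09. Immediate early genes rose in 12 of 19 and fell in 1 (median 0.49, centred 0.86, quantile 0.09, percentile 84.8 among random lists of like level, camera adjusted p = 4.07e-06), with Cd69 up by 2.39 ± 0.18 and Dusp1 by 2.04 ± 0.16. The interferon and immediate early counts were the same adjusted over the list alone. All 4 calls were lost, with adjusted p of 0.232, 0.162, 0.109 and 0.232 in that order with an estimated correlation. Medians with the positive control covariate were 0.35, 0.25, 0.98 and 0.64, and all but the naive and memory list were called (adjusted p = 0.373, 0.00777, 1e-06 and 0.0296).

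Myc and ribosome biogenesis rose in 17 of 22 and fell in 3 (median 0.49, centred 0.85, camera adjusted p = 3.5e-08), with Ncl up by 2.99 ± 0.10 and Myc by 0.67 ± 0.09. Glycolysis rose in 4 of 15 and fell in 1 (median 0.15, centred 0.51, camera adjusted p = 0.00171), with a median of -0.18 after quantile normalization and Slc2a3, a glucose transporter, up by 1.34 ± 0.09. Cholesterol synthesis rose in 6 of 16 and fell in 2, and 5 rose and 1 fell adjusted over the list alone (median 0.15, centred 0.52, quantile 0.06, camera adjusted p = 0.00212), with Srebf2, a regulator of sterol genes, up by 1.61 ± 0.05 and Hmgcs1 by 1.35 ± 0.18, or -0.72 with the covariate. The unfolded protein response and amino acid stress list rose in 8 of 20 and fell in 7, and 9 rose and 8 fell adjusted over the list alone (median 0.08, centred 0.44, quantile -0.11, camera adjusted p = 0.0227), with Hsp90b1 up by 2.52 ± 0.11. The BCL2 family and survival kinases rose in 8 of 17 and fell in 5 (median 0.09, centred 0.45, camera adjusted p = 0.0284), with the kinase Pim1 up by 2.01 ± 0.15 and Bcl2l11 by 1.92 ± 0.07. The Myc, glycolysis and BCL2 counts were the same adjusted over the list alone. These calls were lost, with adjusted p from 0.109 to 0.385 with an estimated correlation. Among random lists of like level, the Myc, glycolysis, cholesterol, unfolded protein and BCL2 lists stood at percentiles 87.7, 46.9, 66.1, 50.8 and 55.5, and the random medians were 0.23, 0.17, 0.07, 0.07 and 0.07. With the covariate the medians of the glycolysis, cholesterol, unfolded protein and BCL2 lists turned to -0.23, -0.46, -0.16 and -0.21 and were not called (adjusted p = 0.957, 0.275, 0.957 and 0.957), and that of the Myc list was 0.07 (adjusted p = 0.0236).

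Oxidative phosphorylation rose in 5 of 25 and fell in 8 by both adjustments and was not shifted (camera adjusted p = 0.394), with a median of -0.06, a mean of -0.08, a test direction that was up, a centred median of 0.30 and a median of -0.31 after quantile normalization. In the main fit the list stood at percentile 3.83 among random lists of like level. With the positive control covariate it was shifted down (median -0.67, adjusted p = 0.00248). Sdha rose by 1.33 ± 0.16, and was at -0.36 with the covariate, and Ndufb8 fell by 0.99 ± 0.09. Heat shock genes rose in 4 of 9 and fell in 4 by both adjustments and were not shifted (camera adjusted p = 0.111), with a median of -0.08, a mean of 0.49, a test direction that was up and a centred median of 0.28, and Hsp90aa1 rose by 2.25 ± 0.18. Of 15 p53 targets 4 rose and 7 fell by both adjustments. They were not shifted (camera adjusted p = 0.565), with a median of 0.00, a mean of -0.07, a test direction that was up and a centred median of 0.36. Bbc3 fell by 0.87 ± 0.06, and Trp53inp1 rose by 1.15 ± 0.14 and was at -0.41 with the covariate.

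Markers of other cells fell in 8 of 13 B cell, 8 of 12 monocyte and macrophage, 9 of 11 neutrophil, 7 of 12 dendritic cell, 5 of 7 platelet, 1 of 5 CD4 T cell and 4 of 7 NK cell genes, and 1, 1, 0, 1, 1, 1 and 1 rose. Adjusted over the list alone, 6 dendritic cell markers fell and the other counts were the same. The medians were -0.29, -0.38, -0.49, -0.30, -0.32, -0.05 and -0.24 as deposited and 0.07, -0.01, -0.13, 0.07, 0.04, 0.31 and 0.12 with centred arrays. All 4 erythroid markers fell, with a median of -0.40, and -0.03 with centred arrays. Camera called none of the 7 lists (lowest adjusted p 0.124). The CD4 list had a mean of 0.34, opposite in sign to its median, and the test direction of the CD4 and NK cell lists was up against their medians. Cd79a and C1qc fell by 0.83 ± 0.09 and 0.68 ± 0.12 and Xcr1 by 0.63 ± 0.16, all from or to levels near or below the background controls, and they were at 0.03, 0.59 and 0.06 with the positive control covariate. Ighm, Bst2 and Cd7 rose by 1.23 ± 0.15, 0.95 ± 0.23 and 0.61 ± 0.15 and were at -0.46, -1.38 and -0.97 with it. The calls of a pair of these genes were lost after quantile normalization, Xcr1 (adjusted p = 0.117) and Cd7 (adjusted p = 0.116). The markers of the sort, Cd8a and Thy1, rose by 1.56 ± 0.15 and 1.03 ± 0.11 and were at -0.26 and -0.20 with the covariate.

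Between anti-CD27 and anti-PD-1/L1 limma called 21674 genes (70.8%), 5238 up and 16436 down, and 22570 had an unadjusted p under 0.05. The split was 11549 up and 5155 down with centred arrays and 7140 and 8247 after quantile normalization. Of the calls, 2926 were at least 2-fold, 1977 up and 949 down, and 20777 had no overlap between arrays, where chance gives 10% of genes not selected by their p. Camera called 16 of 29 lists, all up, and 0 with an estimated correlation, while fry, which asks only whether a list's genes moved on balance, called all 29, with 19 up and 10 down. With the positive control covariate 2412 genes were called, while the median size of the differences called in the main test went from 0.516 to 0.46, the median SE from 0.0848 to 0.304, and 68% of them kept their sign.

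Both treatments with anti-CD27 differed from anti-PD-1/L1 in the same direction in 20174 genes, 4911 up and 15263 down, Mki67, Il7r and Cbl among the former and Rnu2-10 and Rny1 among the latter. Independent lists of these sizes would share 994 and 8760.5 genes. Unchanged groups set against the same 3 arrays shared 0 in 20 simulations, but groups without change give few calls by design, so this 0 does not test the overlap. In 54 genes the calls had opposite directions, among them Gzmb, which was higher in the combination and lower in anti-CD27 than in anti-PD-1/L1. Across genes, which are not independent replicates, the differences correlated at r = 0.968, against 0.831 in the simulations, with a covariance of 0.43 against 0.012. Both comparisons use the same 3 anti-PD-1/L1 arrays, which are too few to be divided between them. The differences of these arrays in control probe sets enter both comparisons, so the shared genes cannot be told apart from them as an effect of anti-CD27. With the positive control covariate 1807 genes were called in the same direction in both.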

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

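The prediction about RNA from other cells was written before its test was run on these arrays, while the tests of labelled RNA and of unequal distributions were chosen after seeing the result. Of the control probe sets, which the comparisons of genes do not use, those for background, bacterial and phage RNA and ERCC RNA had higher signals on the anti-PD-1/L1 arrays than on the others, while the positive controls were lower. Background control probe sets were 0.79 higher (log2) than in anti-CD27 and 0.81 higher than in the combination. Bacterial and phage control probe sets were 1.15 higher than in anti-CD27 and 1.15 higher than in the combination. Probe sets of the ERCC spike-in RNAs were 0.75 higher than in anti-CD27 and 0.74 higher than in the combination. The sources used here do not say whether ERCC RNAs were added to the samples.

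The anti-PD-1/L1 arrays stood apart from the other 6, with 22140 and 21674 genes called against them. Less or poorer labelled RNA on these arrays predicts higher added controls with lower cell transcripts, and the added bacterial and phage controls were 1.15 higher while the positive controls were 1.06 and 0.95 lower, so this explanation may account for part of the calls. Unequal value distributions predict that quantile normalization removes the calls, and after it 15387 genes were called between anti-CD27 and anti-PD-1/L1. Of the 21674 main calls 11407 were kept, and the share of calls that rose went from 24.2% to 46.4%. Unequal distributions may therefore account for part of the calls. RNA from other cells predicts high levels of their markers, and the highest anti-PD-1/L1 mean among those over 0.5 higher than in anti-CD27 was 5.09 (log2), for Pf4, which was at 4.51 in anti-CD27 and 4.55 in the combination. Treatment and array differences fell on the same 3 arrays, so an effect of treatment on these genes remains open and was not tested apart from them.

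The real grouping was compared with every other split of the 6 arrays of each comparison. In each of the 3 comparisons only 1 of 10 splits, the real one, gave at least as many genes as were called, and the highest count among the others was 0. With 10 splits the share cannot be under 0.05, so these splits are too few to tell the real grouping from others at that level.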

How the results depend on the processing

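Array weights per group, the positive control covariate, and for gene lists the stricter filter and the 6-array fit were chosen after seeing the data. Genes called between the combination and anti-PD-1/L1, between anti-CD27 and anti-PD-1/L1, and in the same direction in both numbered 42358, 42213 and 38155 with all transcript probe sets, 11875, 11414 and 10739 without the lowest 50% of genes, where fewer genes were tested, and 1910, 2412 and 1807 with the covariate, which follows the groups and raised the median SE from 0.0855 to 0.338 and from 0.0848 to 0.304. A minimum of 1.5-fold left 9700, 8798 and, between the combination and anti-CD27, 269. The last comparison had 1645 calls with its 6 arrays alone, 2502 with array weights and 2192 with weights per group. The main fit pools the SD of all groups (median 0.141 in anti-PD-1/L1, 0.0682 and 0.0586 in those compared), so its count here is cautious. Leave-one-out counts ran from 19776 to 22586, from 174 to 1218 and from 19029 to 22156 for the combination against anti-PD-1/L1, the combination against anti-CD27 and anti-CD27 against anti-PD-1/L1, and from 18100 to 20978 for the shared calls, while 19, 17 and 16 lists were called in every such fit. An estimated correlation left 0, 5 and 0 lists and the covariate 5 (combination) and 8 (anti-CD27) against anti-PD-1/L1, where fry called 29 for anti-CD27. Counts within 1.5 times the main ones came from the filter on the lowest 25% of genes (17779, 655 and 17200), the trended and robust prior (22104, 500 and 21624), and the replicate number as a block (21644, 375 and 21054, with 19677 shared calls and 19, 17 and 16 lists). Equal replicate numbers did not pair arrays: their deviations correlated at -0.2 to 0.16 over 9 pairs, and 3 of 9 arrays were closest to one with their own number. Between the combination and anti-CD27 no named gene reversed. Reversed were Pdcd1 in anti-CD27 against anti-PD-1/L1 with centred arrays (0.266), and after quantile normalization Pdcd1 in the combination against anti-PD-1/L1 (-0.267) and Tbx21 in anti-CD27 against anti-PD-1/L1 (-0.407); the cause was not tested. With the covariate, in the combination against anti-PD-1/L1, these reversed: AF357399 0.744, Rn5s 0.154, Ifng -1.029, Sdha -0.498, Cycs -0.785, Hmgcs1 -0.398, Trp53inp1 -0.813, Cd79a 0.084, Cd68 -0.462, Bst2 -1.806, Cd7 -0.852, Pdcd1 -0.131, Cd274 -0.012, Cd8a -0.701, Thy1 -0.391 and Prf1 -0.136. In anti-CD27 against anti-PD-1/L1 they were AF357399 0.496, Rn5s 0.103, Ifng -0.99, Sdha -0.356, Hmgcs1 -0.725, Trp53inp1 -0.408, Ighm -0.458, Cd79a 0.033, C1qc 0.592, Bst2 -1.383, Xcr1 0.058, Cd7 -0.974, Cd8a -0.258, Thy1 -0.204, Prf1 -0.256 and Klrg1 0.123. None of these passed with the covariate (adjusted p from 0.128 to 0.992 and from 0.173 to 0.973), and the cause was not tested. Limiting the list members named against anti-PD-1/L1 to 2, a limit set after the values were seen, also limited the genes listed here. Background control probe sets had means of 3.25, 3.27 and 4.06 in the combination, anti-CD27 and anti-PD-1/L1, so differences of genes near these levels are limited by background.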

Other observations

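The genes in this part outside the named-gene rule were chosen after their values were seen, and of its tests of explanations the one on array quality was written beforehand and the one on NK cells after seeing the result. Some genes set the combination apart from both single treatments and kept both calls when any 1 array was left out. Gpr15, a chemoattractant receptor that guides T cells to the colon, was higher in the combination by 1.84 ± 0.11 (log2 difference ± SE, n = 3) than in anti-PD-1/L1 (limma adjusted p = 2.02e-06) and by 1.81 ± 0.11 than in anti-CD27 (adjusted p = 0.000298). Mt1, which encodes the metal-binding metallothionein 1, was higher by 1.76 ± 0.14 and 1.91 ± 0.14, and Kcnk5, a potassium channel gene, by 1.09 ± 0.07 and 1.67 ± 0.07. Lilr4b, a relative of Lilrb4a, was higher by 2.29 ± 0.09 and 1.32 ± 0.09, and Pclaf, a PCNA-binding factor of replicating cells, by 1.83 ± 0.13 and 1.36 ± 0.13. Klk8, a serine protease gene, was lower by -1.48 ± 0.06 and -0.53 ± 0.06, and Slc6a19, an amino acid transporter gene, by -0.60 ± 0.09 and -0.80 ± 0.09. These genes kept their sign against anti-PD-1/L1 with the positive control covariate, with 2.03 for Gpr15 and 2.28 for Mt1. In all, 352 genes were higher and 49 lower in the combination than in both single treatments, where independent lists would share 73.3 and 85.3. In 92 genes the calls had opposite directions. The differences correlated across genes at r = 0.361, against 0.326 in 20 simulations of unchanged groups that share the combination arrays. Those groups shared 0 genes, which does not test the overlap, since groups without change give few calls by design. Calls against anti-PD-1/L1 covered 72.3% of all genes, and array differences fell on the same arrays.

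Small structured RNAs were grouped by symbol after their values were seen and were not tested against other genes. Their 94 genes had a median of -0.92 in anti-CD27 against anti-PD-1/L1, -0.96 in the combination against anti-PD-1/L1 and -0.09 between the combination and anti-CD27. The median of all genes was -0.26 in both comparisons with anti-PD-1/L1, and with centred arrays the medians of the small RNAs were -0.55 and -0.58. With the positive control covariate Rn5s was at 0.10 and 0.15 and AF357399 at 0.50 and 0.74, while the other small RNAs named above stayed negative, with none past the threshold (Rny1 -1.39 and -1.30). Differences within the anti-PD-1/L1 group resembled in part those between groups: the difference of its replicates 1 and 3 correlated across genes at r = 0.38 with that of anti-CD27 and replicate 2, and at 0.43 among the 50% of genes with the highest means. Genes are not independent replicates, and no p is given for these correlations.

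More S phase and cytotoxic transcripts were found in the combination than in anti-CD27. Array quality predicts a smaller shift with the positive control covariate, and the S phase median went from 0.82 to 0.84. The covariate's slope is set mostly by the anti-PD-1/L1 arrays, so this test cannot exclude array quality. The cytotoxic median went from 0.29 to 0.16, so a part may follow array quality, and the list stayed shifted (camera adjusted p = 8.67e-08). NK cells among the sorted cells predict a rise of NK cell markers, and the median of 6 markers was 0.01, with a range of -0.15 to 0.30, against 0.61 for 13 NK-type receptors that effector CD8+ T cells can also carry. Whether blockade of PD-1 and PD-L1 changed these cells remains open and was not tested apart from transcripts.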
